A study of Mus musculus with 6 samples.

How the data were processed

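RNA was measured in 6 mouse kidney samples, 3 labelled DHT and 3 labelled control. Per the labels' protocols, total RNA was extracted with Trizol and mRNA libraries were made by standard Illumina methods. Per the submitters' processing notes, HISAT2 2.0 and the genome build mm10 were used. Tnf and most genes near it had 0 counts in all libraries and are not measured by this table. The counting tool, its annotation, the strand setting, the treatment of reads that fit several places and any filter are not given in the sources used here. The deposited table holds raw counts per gene symbol for the 6 libraries, whole numbers with no normalization, in 46095 rows, of which 20681 have no count. Each column was matched to its sample by the sample's title. A set of 27 rows bear dates in place of gene symbols, as a spreadsheet makes of certain names, and 2 of these dates stand on 2 rows each, kept apart. They hold 0.142% of counts, 20 were tested and 0 were called, and they were given no gene name.

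Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the group (minimum count 10, minimum total 15), leaving 15367, and scaled by TMM. A robust quasi-likelihood fit with the group as its single term was tested with Benjamini-Hochberg adjustment at 0.05. SE values are those that the F statistic implies for the log2 fold change. CPM values use TMM-scaled library sizes, with SD over 3 libraries. Gene lists (43, fixed by membership) were tested with limma 3.58.1's camera at a preset correlation of 0.01 where at least 5 members were tested, which left 38, with adjustment over lists. The same test with an estimated correlation and fry were alternatives. The 5 smaller lists, neutrophil, adrenal, muscle, urothelium and sex chromosome genes, were not tested as lists, and values are given for some of their members. Counts of called list members are over all genes tested and adjusted over the list alone.

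The groups, tests, lists, alternatives and the rule for named genes were set before the data were examined. The rule took the 12 largest increases and 12 largest decreases among called genes with a mean of at least 1 CPM, no overlap between groups and a proper symbol, up to 4 members of each list by smallest p, and a few genes of the study's question (among them Tnf, its receptors, NF-kB subunits and Nfkbia, Bax, Bcl2, Havcr1, Lcn2 and Kap). Some genes met by this rule are not reported here. Other genes named in the text, such as Gusb, Cry2, Per2, Per3 and the members of gene families, were chosen after their values were seen, as were the length and GC corrections and the check of the genes near Tnf.

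Alternatives were median-ratio size factors, total counts, no low-count filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a fit with no robust step, a replicate block, other thresholds and leaving out each library in turn. Length and GC corrections removed a loess trend (span 0.3) of each library's log expression. The deposited counts were matched by symbol to GENCODE M21 gene models on GRCm38, the assembly of mm10; 93.0% of tested genes and 94.1% of called genes had a length. Overlapping exons were found with bedtools 2.31.1 and near-identical transcripts (95% identity over at least 50% of the transcript) with BLAST 2.17.0+. Of 190 genes named by the rule, 42 share exonic bases with another gene, 35 of them on the opposite strand, and 9 have a near-identical transcript elsewhere; as strand use is not given, reads of such genes cannot be told apart.

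Depth was 15.05 to 19.33 in units of 1e6 counts per library, and the common biological coefficient of variation was 0.217. Mitochondrial genes took 11.4% to 14.9% of counts. Pairs of libraries differed by far more than sampling noise, so none was counted as a repeat. Simulated counts with 200 changed genes of 15035 tested gave 12%, 54%, 92% and 96% calls at 1.5-, 2-, 4- and 8-fold, with 14 false calls and 0 called in the wrong direction. The changed genes were drawn only from genes above a minimum mean count, so these rates do not cover genes with few counts. In simulated counts with 1 list shifted by 0.5 log2, that list was found and 0 others of 38. Genes were drawn independently there, so false list calls from correlated members could not show. In the real libraries the estimated correlation was, for example, 0.628 in the list of androgen-raised genes.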

Results

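Gene expression was measured by RNA sequencing in kidney samples of mice on a C57BL/6 background. The treatment label names DHT (dihydrotestosterone, a potent androgen) for 3 samples and control for 3. In mice, DHT exposure is used to model polycystic ovary syndrome (PCOS), a hormonal disorder of females, and the study asked whether tumour necrosis factor (TNF), NF-kB signalling, inflammation and apoptosis accompany kidney injury in that model. The strain label names the PCOS model for control kidneys too, so the groups rest on the treatment label. Total counts, in units of 1e6, were 17.12, 15.05 and 18.62 in DHT replicates 1, 2 and 3, and 15.99, 19.33 and 18.44 in control replicates 1, 2 and 3. Xist, the RNA of the silenced X chromosome, had 6882 to 15136 counts per library, and the Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d had 0 counts in all 6 libraries. The labels do not say that the 3 replicates of a group are separate animals, so p-values measure the spread between these samples.

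Among the largest increases in DHT were the transporter genes Slco1a1 and Slc7a13 and the enzyme genes Cyp2j13 and Ugt2b37, and among the largest decreases Slc17a2, Hdc, Npas2, Loxl4 and Arntl. Of 15367 genes tested with edgeR's quasi-likelihood test, 437 passed a Benjamini-Hochberg adjusted p of 0.05. Of these, 212 were higher and 225 lower in DHT, and 104 and 113 of them differed by at least 2-fold. All 437 had non-overlapping groups, a state found in 29.8% of all tested genes where chance gives 10%. The count depended on single libraries: it was 0 without DHT replicate 3, 7 without control replicate 2, 19 without DHT replicate 1, 89 without control replicate 3, 366 without control replicate 1 and 1224 without DHT replicate 2. The first principal component held 46.8% of the variance and parted the groups, with DHT replicate 2 at -13.9 against -45.0 and -46.6 for the other DHT libraries and 27.3 to 42.6 for the controls.

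The androgen-responsive genes of the mouse kidney, a list fixed in advance, were the group with the largest shift. Slco1a1 (chromosome 6, 141907282 to 141946962, GRCm38), an organic anion transporter of the proximal tubule, went from 0.116 ± 0.159 to 416 ± 411 counts per 1e6 (CPM; mean ± SD, n = 3 each, log2 fold change 11.62 ± 1.69 SE, edgeR adjusted p = 0.0347). The controls held 7 Slco1a1 counts in all against 20221 in DHT, a pooled ratio of 3300 with a 95% exact interval of 1600 to 8220 that covers counting error alone. Of the 7, control replicate 3 holds 6, control replicate 2 holds 1 and control replicate 1 holds 0, so the ratio rests on control replicate 3: without it the log2 fold change of the gene Slco1a1 was 13.51 (adjusted p = 0.104). Its call was also lost without control replicate 1 (0.0808), control replicate 2 (0.139), DHT replicate 1 (0.0629) or DHT replicate 3 (0.108), with limma-voom (0.113) and with no low-count filter (0.0799). Cyp2j13 (chromosome 4, 96027534 to 96077546), a cytochrome P450, rose from 0.795 ± 0.363 to 373 ± 288 CPM (log2 fold change 8.89 ± 1.22, edgeR adjusted p = 0.0343). Cyp4b1 (chromosome 4, 115624725 to 115647723), another cytochrome P450, rose from 189 ± 52.4 to 2910 ± 1510 CPM, a log2 fold change of 3.95 ± 0.50. Cyp2e1, which oxidises ethanol and other small molecules, rose from 83.8 ± 37.9 to 1530 ± 910 CPM, Timd2, a cell surface ferritin receptor, from 8.62 ± 1.85 to 50.6 ± 15 CPM, and Gusb, the lysosomal beta-glucuronidase long used as an androgen-induced kidney enzyme, by 0.67 ± 0.13 on the log2 scale. Slc22a30 also rose, from 11.7 ± 0.941 to 176 ± 137 CPM, but 57.2% of its transcript is 98.9% identical to Slc22a28, so the 2 genes are uncertain, and with the length correction its log2 fold change was 3.88 and its adjusted p 0.0531.

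Of the 20 list members tested, 7 were higher and 0 lower over all genes, and 18 were higher when adjusted over the list alone. Kap, the kidney androgen-regulated protein, did not pass: it stood at 16000 ± 9030 CPM in DHT and 5610 ± 3520 CPM in control (log2 fold change 1.51 ± 0.71, edgeR adjusted p = 0.251), with control replicate 1 at 1550 CPM and DHT replicate 2 at 5690 CPM. The list ranked above other genes by camera with a preset correlation (adjusted p = 3.6e-21). It did not do so with an estimated correlation (adjusted p = 0.669 with an estimated correlation). Its median shift over the control mean was 3.02 and 2.68 log2 in DHT replicates 1 and 3 and 1.05 in DHT replicate 2. The number of members higher was 14 without DHT replicate 2, 3 without control replicate 1, 1 without DHT replicate 1 or control replicate 3, and 0 without DHT replicate 3 or control replicate 2.

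**Figure D1:**
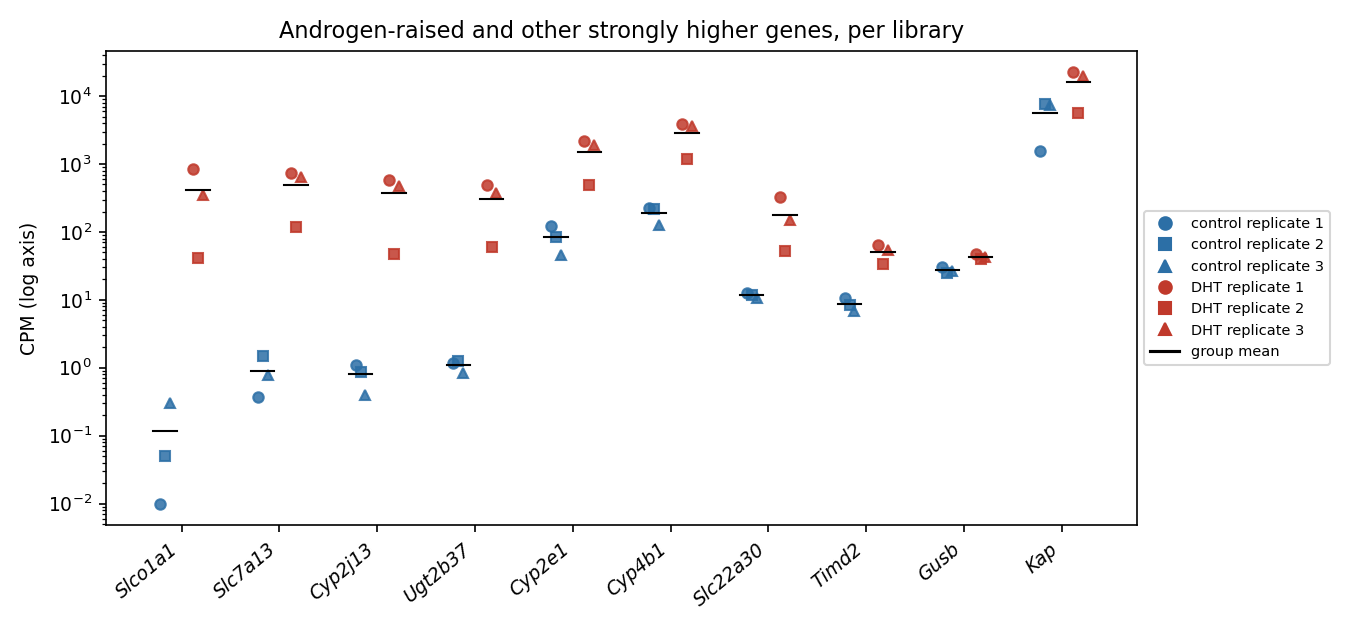
CPM on a log axis for 10 genes in each of the 6 libraries, with symbols for replicates and bars for group means; a count of 0 is drawn at 0.01 CPM. DHT libraries lie above controls except for Kap, where DHT replicate 2 (5690 CPM) lies among the controls, and DHT replicate 2 is the lowest DHT library for each gene.

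Of 8 tested kidney genes that are higher in females than in males, 1 passed over all genes, Slc22a29, an organic anion transporter relative that fell from 55.6 ± 14.7 to 7.69 ± 4.66 CPM (log2 fold change -2.85 ± 0.47, edgeR adjusted p = 0.0385). Its transcript is 96.8% identical to Slc22a27 over 91.9% of its length, so the value is uncertain. Adjusted over the list alone, 3 were lower and 1 was higher; over all genes 0 were lower without DHT replicate 1, DHT replicate 3, control replicate 2 or control replicate 3, and 2 without DHT replicate 2 or control replicate 1. Without DHT replicate 2, 1 was also higher, Slc22a28 (log2 fold change 2.88, adjusted p = 0.0229). The amino acid transporter Slc7a12 was at 61.7 ± 14.9 CPM in DHT and 305 ± 223 CPM in control, and the efflux pump Abcc3 at 7.60 ± 3.38 and 86.3 ± 70.1 CPM. Neither passed (edgeR adjusted p = 0.14 and 0.0931), and the list did not pass camera (adjusted p = 0.0779, and 0.669 with an estimated correlation).

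The TNF and NF-kB genes that the study is about showed a single call. Cxcl1, a neutrophil-attracting chemokine (chromosome 5, 90891241 to 90893115), was higher in DHT, at 2.87 ± 2.01 CPM against 0.375 ± 0.216 CPM (log2 fold change 2.94 ± 0.64, edgeR adjusted p = 0.0491, from 139 and 20 counts). It was the only called member of 30 TNF and NF-kB targets tested, over all genes and when adjusted over the list alone; without DHT replicate 2 Tnfaip2, a TNF-induced gene, was also called, lower (adjusted p = 0.0397). The gene Cxcl1 kept its call with DESeq2 (adjusted p = 0.00057) and without DHT replicate 2 (0.0178). It lost it with total counts (0.0543), limma-voom (0.0758), no robust step (0.0503), the replicate block (0.0671) and the length correction (0.0669). It also lost it without control replicate 1 (0.0541), control replicate 2 (0.165), control replicate 3 (0.12), DHT replicate 1 (0.133) or DHT replicate 3 (0.139). Nfkbia, the inhibitor that NF-kB induces to end its own signal, was at 33.4 ± 6.71 CPM in DHT and 21.8 ± 1.90 CPM in control and did not pass (edgeR adjusted p = 0.0766). Nfkb1 and Rela, the subunits of NF-kB, had log2 fold changes of -0.01 ± 0.17 and 0.10 ± 0.13 (edgeR adjusted p = 0.986 and 0.686). As a list the targets did not pass camera (adjusted p = 0.11, and 0.914 with an estimated correlation). That p was 0.00017 without DHT replicate 1, 0.0397 without control replicate 3 and 0.0495 without DHT replicate 3, and 0.872 with the direction downward without DHT replicate 2.

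Tnf itself (chromosome 17, 35199381 to 35202007, GRCm38) had a count of 0 in all 6 libraries. So had 30 of the 37 protein-coding genes within 250 kb of it, Tnf included, against 21.3% of all 20612 protein-coding genes matched. Among those at 0 were Bag6, Csnk2b, Clic1 and Prrc2a, which most tissues express. The 0 at Tnf is thus not a measurement of its expression, and no fold change is given. Neighbouring members of the fixed lists were affected alike: Aif1 and Ltb had 0 counts, Hspa1a 17 and Hspa1b 7 over the 6 libraries.

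TNF receptors and NF-kB signal transducers held 0 called genes among 20 tested, also when adjusted over the list alone. Tnfrsf1a, the main TNF receptor, was at 70.6 ± 12.7 CPM in DHT and 66.7 ± 7.84 CPM in control, and Tnfrsf1b, the other receptor, at 9.73 ± 8.13 and 6.29 ± 1.95 CPM, with 19.1 CPM in DHT replicate 2. The kinase genes Chuk and Ikbkb had log2 fold changes of 0.49 ± 0.20 and -0.35 ± 0.14 (edgeR adjusted p = 0.18 and 0.178). Camera gave adjusted p = 0.904.

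Apoptosis genes held 0 called genes among 38 tested, also when adjusted over the list alone, and 1 was higher without DHT replicate 2. Camera gave adjusted p = 0.679 (0.914 with an estimated correlation). Casp8, the initiator caspase of death receptors, was at 37.4 ± 2.54 CPM in DHT and 27.0 ± 4.77 CPM in control (edgeR adjusted p = 0.109), and Endog, a mitochondrial nuclease, at 27.3 ± 8.76 and 15.4 ± 2.73 CPM (adjusted p = 0.0892). Bax and Bcl2, which promote and block apoptosis, had log2 fold changes of 0.08 ± 0.12 and 0.01 ± 0.16. A p above the threshold does not show equal expression: in simulated libraries with this spread, 54% of genes changed 2-fold were called and 12% of those changed 1.5-fold. Those genes lay above a minimum mean count, so the rates do not cover genes with few counts.

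Markers of tubular injury showed 1 called gene of 23 tested. Plin2, a lipid droplet coat protein, rose from 60.4 ± 2.74 to 109 ± 5.62 CPM (log2 fold change 0.85 ± 0.10, edgeR adjusted p = 0.0142). Adjusted over the list alone, 2 were higher and 0 lower; over all genes 0 were called without DHT replicate 1, DHT replicate 3 or control replicate 2, and 2 higher and 1 lower without DHT replicate 2. Havcr1 (kidney injury molecule 1) had 43 counts in DHT and 36 in control, at 0.883 ± 0.0562 and 0.606 ± 0.540 CPM (edgeR adjusted p = 0.74). Lcn2 (neutrophil gelatinase-associated lipocalin) was at 1.97 ± 1.19 CPM in DHT and 3.84 ± 4.91 CPM in control, with 9.50 CPM in control replicate 3. Spp1, or osteopontin, was at 1340 ± 369 and 1970 ± 395 CPM, and Krt8, an epithelial keratin, at 107 ± 16.9 and 65.0 ± 13.9 CPM, neither past the threshold (edgeR adjusted p = 0.207 and 0.0668). The list's median log2 fold change was -0.06 and its mean 0.03, and camera, with its direction upward, gave adjusted p = 0.62. Fry's mixed test passed the list (adjusted p = 0.0213). That test asks whether members change in either direction, not whether they change more than other genes. Of 31 fibrosis and matrix genes 0 were called, against 3 lower without DHT replicate 2, while camera placed the list lower (adjusted p = 0.0401), a call that was lost with an estimated correlation (adjusted p = 0.914). The list did not part the groups: its library medians were -0.71, 0.10 and -0.46 in DHT replicates 1, 2 and 3 and 0.08, -0.44 and 0.36 in control replicates 1, 2 and 3, and 8 of 10 divisions of the libraries gave as small a p, the real one counted. Fn1, or fibronectin, was at 28.3 ± 6.76 CPM in DHT and 44.1 ± 10.1 CPM in control.

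**Figure D2:**
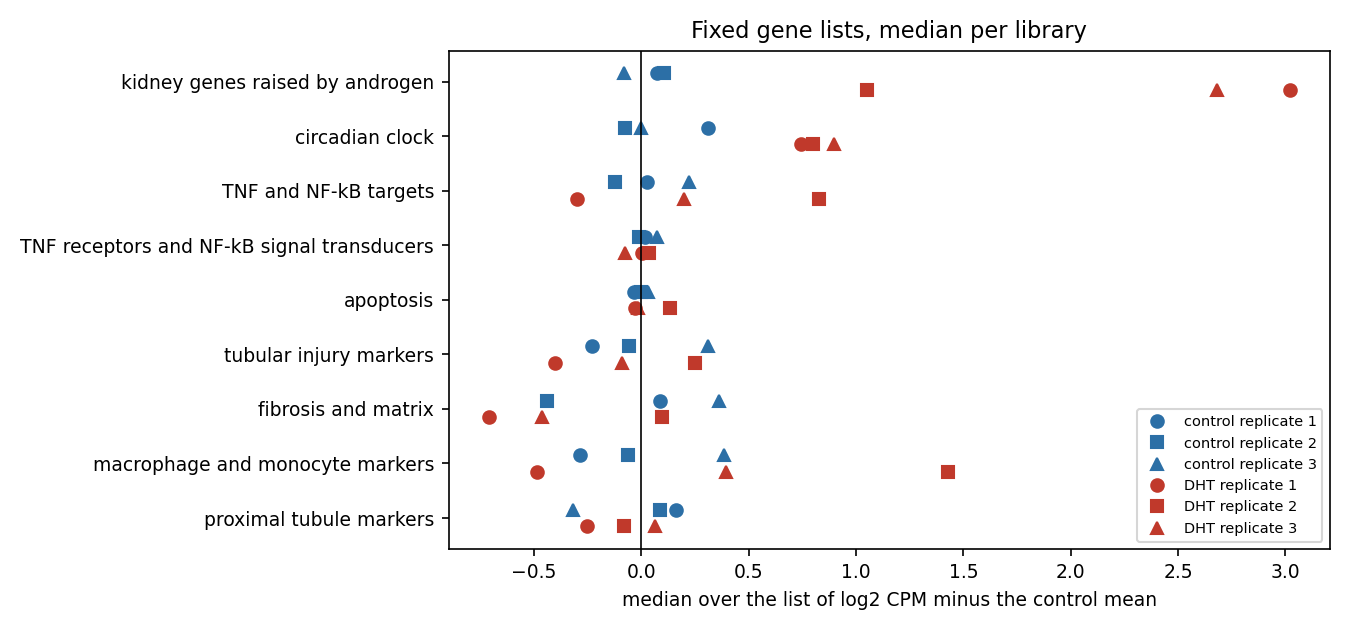
Median over each of 9 fixed gene lists of log2 CPM relative to the control mean, 1 point per library, with symbols for replicates. Androgen-raised genes lie at 1.05 to 3.02 in DHT libraries, and macrophage markers at 1.43 and TNF and NF-kB targets at 0.825 in DHT replicate 2 alone stand above the other libraries.

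Cell type markers set DHT replicate 2 apart. Macrophage and monocyte markers stood at 1.43 log2 above the control mean there, against -0.49 and 0.39 in DHT replicates 1 and 3, and 0 of 16 were called. Camera placed that list higher (adjusted p = 0.0401), and not with an estimated correlation (adjusted p = 0.914). The list did not part the groups, with medians of -0.29, -0.06 and 0.385 in control replicates 1, 2 and 3. As small a camera p came from 7 of 10 divisions of the libraries, the real one counted. C1qb, a complement component made by macrophages, was at 50.2 CPM in DHT replicate 2 and 34.1 ± 16.4 CPM over the DHT group. Red blood cell markers had a median of 1.61 in DHT replicate 2 against -1.87 and -1.68 in DHT replicates 1 and 3, and lymphocyte markers 0.94 against -0.27 and 0.14. In control replicates 1, 2 and 3 the red blood cell medians were 0.09, 0.865 and -1.07. The lymphocyte medians there were -0.54, 0.004 and 0.42. Endothelial markers had a median of 0.64 in DHT replicate 2 and 1 of 12 called, Ehd3, which rose by 0.76 ± 0.12 log2 (edgeR adjusted p = 0.0261). Of 25 proximal tubule markers 1 was called lower, the amino acid transporter Slc7a8 (160 ± 38.3 against 414 ± 102 CPM, edgeR adjusted p = 0.0345). Slc7a13, a transporter of the straight segment that carries aspartate, glutamate and cystine, was the called gene of 10 straight segment markers, rising from 0.888 ± 0.574 to 499 ± 335 CPM (log2 fold change 9.10 ± 1, edgeR adjusted p = 0.0201). Adjusted over the list alone, 2 proximal tubule markers were higher and 3 lower, and 3 straight segment markers were higher. Without DHT replicate 1, DHT replicate 3 or control replicate 2 none of these 3 lists held a call, and without DHT replicate 2 the proximal tubule list held 4 higher and 2 lower and the straight segment list 4 higher. Without control replicate 3 the endothelial and straight segment lists held 0, and without control replicate 1 the straight segment list held 1 higher and 1 lower. Markers of the loop of Henle, distal tubule, principal cells, intercalated cells, podocytes, mesenchymal cells, lymphocytes, fat cells and red blood cells held 0 calls over all genes, with 2 intercalated cell, 2 distal tubule and 1 mesenchymal marker passing over the list alone. Without control replicate 1 the loop of Henle and fat cell lists held 1 lower each, and without DHT replicate 2 the mesenchymal and red blood cell lists 1 lower each. None of these lists passed camera (adjusted p between 0.0779 and 0.836). Control replicate 3 also stood apart: loop of Henle markers had a median of 0.66 there against -0.60 and -0.03 in control replicates 1 and 2. Principal cell markers were at 0.56 in control replicate 3 against -0.28 and -0.12.

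Circadian clock genes moved in both directions. Arntl and Npas2, which encode activators of the core loop, fell, Arntl from 25.9 ± 8.18 to 1.67 ± 1.23 CPM (log2 fold change -3.94 ± 0.58, edgeR adjusted p = 0.0295) and Npas2 from 13.7 ± 7.07 to 0.758 ± 0.227 CPM (-4.17 ± 0.47, adjusted p = 0.0136). Nfil3, a repressor, fell from 13.0 ± 4.95 to 2.94 ± 0.459 CPM. Tef, an output factor, rose from 139 ± 30.8 to 399 ± 66.3 CPM (1.52 ± 0.20, adjusted p = 0.0155), and Ciart, a repressor of the loop, from 0.958 ± 0.448 to 12.3 ± 5.70 CPM, though it has a 96.7% identical pseudogene. Per2, Per3 and Cry2, of the repressor arm, rose by 1.92, 1.71 and 0.87 log2. Over all genes 5 of 18 were higher and 3 lower, and 11 and 4 when adjusted over the list alone. Without DHT replicate 3 or control replicate 2, 0 were called, without DHT replicate 1 0 higher and 1 lower, without control replicate 3 1 and 1, and without control replicate 1 10 and 3. Camera placed the list higher (adjusted p = 5.02e-05), and not with an estimated correlation (adjusted p = 0.546).

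**Figure D3:**
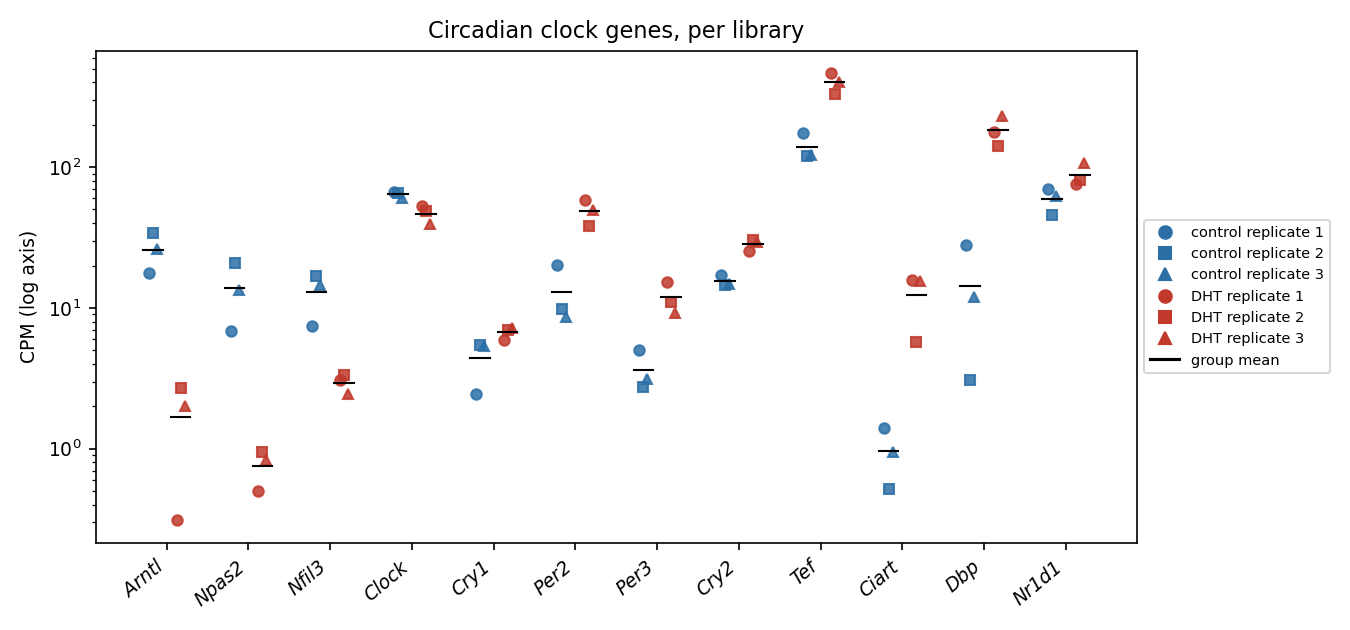
CPM on a log axis for 12 clock genes in each library, with bars for group means. Arntl lies at 17.6 to 33.9 CPM in controls and 0.314 to 2.69 CPM in DHT libraries, and Tef at 120 to 175 and 332 to 465 CPM.

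Among steroid receptors and steroid-metabolising enzymes 2 of 21 were higher, Ugt2b37, a glucuronosyltransferase (1.08 ± 0.215 to 307 ± 223 CPM, log2 fold change 8.14 ± 0.99, edgeR adjusted p = 0.0252), and Hsd3b3, a 3-beta-hydroxysteroid dehydrogenase family member (43.2 ± 8.84 to 108 ± 23.0 CPM, adjusted p = 0.0251), and 8 were higher when adjusted over the list alone. Among 29 fatty acid oxidation genes Eci2, a peroxisomal isomerase (log2 fold change 1.03 ± 0.14), and Plin2 were higher and Ppargc1a, a coactivator of mitochondrial genes, lower (-0.53 ± 0.11). Lnpep, an aminopeptidase, was the called gene of 13 in the renin-angiotensin list (9.88 ± 0.821 to 28.6 ± 5.17 CPM, adjusted p = 0.0125), while Ren1, or renin, at 422 ± 262 against 58.7 ± 37.7 CPM, did not pass (adjusted p = 0.0719). Nqo1, a quinone reductase, was the called gene of 21 in the NRF2 list, at 137 ± 30 against 60.7 ± 13.1 CPM. With the length correction Nqo1 (log2 fold change 1.17 before and 1.01 after, adjusted p = 0.0612) and Ppargc1a (-0.53 and -0.44, 0.0807) lost their calls, as did Ppargc1a with the GC correction (0.0548) and without DHT replicate 2 (0.0519). Over the list alone 8 were higher and 1 lower in fatty acid oxidation, 3 higher in the renin-angiotensin list and 5 higher in the NRF2 list. Without DHT replicate 1, DHT replicate 3 or control replicate 2 none of these 4 lists held a call, and without DHT replicate 2 they held 6, 5, 2 and 3 higher in the order named, with 2 lower in fatty acid oxidation and 1 lower in the NRF2 list. Without control replicate 3 the steroid and NRF2 lists held 0, and without control replicate 1 the NRF2 list held 0. Camera placed these lists higher, with adjusted p between 5.02e-05 and 0.0313, and none passed with an estimated correlation (adjusted p = 0.669 for 3 and 0.732 for fatty acid oxidation). Libraries overlapped in 2 of these lists. The renin-angiotensin median was 0.02 in DHT replicate 2 against 0.12 and 0.06 in control replicates 1 and 2, with 7 of 13 members above 0, and the fatty acid oxidation median was 0.07 in DHT replicate 1 against 0.17 in control replicate 2. The NRF2 list lost its call with the length correction.

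Of 47 ribosomal protein genes 3 were higher, among them Rpl34 and Rps19 (log2 fold changes 0.64 and 0.64), and 13 when adjusted over the list alone, with camera adjusted p = 3.74e-07 and 0.669 with an estimated correlation. Of 63 nuclear respiratory chain genes 1 was higher, Ndufb4 (0.90 ± 0.17), with camera adjusted p = 5.02e-05 and 0.868 with an estimated correlation. Without DHT replicate 1, DHT replicate 3, control replicate 1 or control replicate 2 neither list held a call; without control replicate 3 the ribosomal list held 1, and without DHT replicate 2 the respiratory chain list held 2. Over 14298 genes with a known length, the fold change fell with spliced length (Spearman rho across genes -0.233, genes not being independent replicates). The median log2 fold change was 0.20 in the shortest of 5 equal length classes and -0.10 in the longest. With the length trend removed, the respiratory chain list lost its camera call and the ribosomal list kept it. In that fit 249 genes were called, and Ndufb4 (log2 fold change 0.77 ± 0.15, adjusted p = 0.0516) and Rpl34 (0.57 ± 0.12, adjusted p = 0.0571) were not, while Rps19 was (adjusted p = 0.0458).

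**Figure D4:**
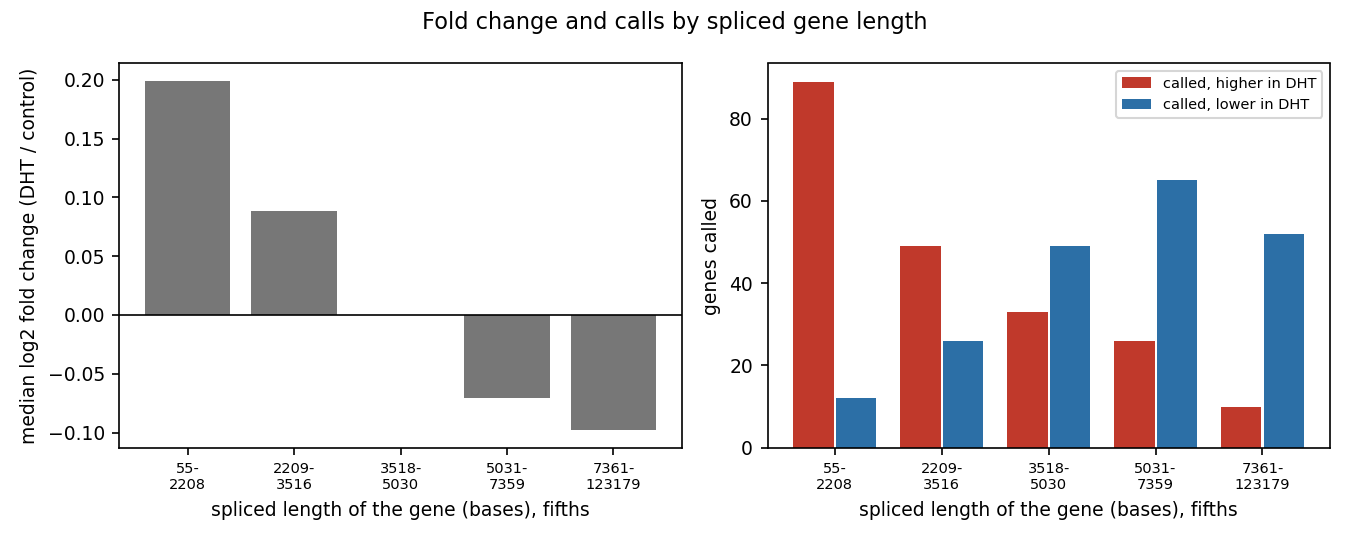
Left, median log2 fold change (DHT over control) for genes in 5 classes of spliced length in bases; right, genes called higher and lower in each class. The shortest class holds 89 called higher and 12 lower, the longest 10 higher and 52 lower.

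Preset-correlation camera called 15 of 38 lists, 13 higher and 2 lower, and 0 with an estimated correlation (smallest adjusted p = 0.546, with 2 lists at an unadjusted p under 0.05) and 0 by fry's directional test. Fry's mixed test passed 15 lists, among them the androgen list (adjusted p = 0.0361) and the circadian clock (0.0213). It did not pass TNF and NF-kB targets (0.23) or apoptosis (0.0949). Other divisions of the same 6 libraries into 3 and 3 gave up to 21 list calls, against 15 between DHT and control. Each has unequal numbers of DHT libraries on its sides, so part of the group difference stays in it. The androgen list reached an unadjusted camera p of 1.29e-14 in another division. Of the 15 lists called, 3 had their smallest camera p between DHT and control. As small a p came from 2 of 10 divisions for the ribosomal, nuclear respiratory chain and steroid lists, the real one counted. For cell cycle, immediate early and heat shock lists it was 4 of 10.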

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

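The length and GC corrections were chosen after the data were seen; the other settings were fixed before. The 437 calls (212 higher, 225 lower) stayed within 1.5 times under median-ratio size factors, the CPM filter, limma-voom and the fit with no robust step. They became 852 (418 higher, 434 lower) with no low-count filter, 1533 (813 and 720) with DESeq2, 249 (121 and 128) with the length correction, 678 (366 higher) with the GC correction, 217 (104 and 113) with a 2-fold minimum and 1528 (767 and 761) at an adjusted p of 0.1. With total counts as the scale 132 were higher, and the median gene moved from 0.003 to -0.101 log2, so that higher calls are relative to that shift; the higher share was 38.8% there and 48.5% in the TMM fit. With a replicate block 85 genes were called (36 higher, 49 lower). Same-numbered libraries' deviations correlated at 0.073, -0.153 and 0.040, and not every sample correlates best with its own number. The correlation across genes of a library's deviation with GC did go with the number. It was -0.1851 and -0.1938 in DHT and control replicate 1, -0.08835 and -0.07837 in replicate 2, and 0.2222 and 0.2498 in replicate 3. Whether the numbers pair the samples is thus not settled. Leaving out a library gave 0 to 1224 calls, 0 to 745 higher and 0 to 479 lower, and with the 0, 2763 genes still had an unadjusted p under 0.05 in edgeR. The cause of these changes was not tested. The sign of the 437 was kept under each setting wherever the gene was tested. Of them, 436 were tested without control replicate 3 and 428 with the CPM filter. As all 437 had non-overlapping groups, leaving out a library could hardly reverse a sign, so this is no separate support. Of the 15 lists called, 0 passed with an estimated correlation and 0 by fry's directional test, while fry's mixed test passed 15 of all lists tested. Leaving out a library gave 12 to 16 list calls by camera. The length correction gave 11, losing the fibrosis, glucocorticoid, macrophage, NRF2 and nuclear respiratory chain lists and gaining the loop of Henle list. The androgen list had camera adjusted p = 0.669 with an estimated correlation, 0.151 by fry's directional test, and 4.33e-67 to 6.59e-16 by camera when a library was left out. TNF and NF-kB targets ranged from 0.00017 to 0.872 and turned downward without DHT replicate 2 (0.872). Apoptosis ranged from 0.379 to 0.884, turning downward without DHT replicate 2 (0.884), and tubular injury from 0.0797 to 0.893, turning downward without control replicate 1 (0.846) and DHT replicate 2 (0.758); the cause was not tested. Of 189 named genes tested, 42 were called, and 0 reversed a call. The 42 are among the 437 with non-overlapping groups, so this too is no separate support. A further 23 uncalled genes changed sign 44 times. The number weakened or gained per setting is largest without DHT replicate 3 or control replicate 2, where 42 of the 42 lost their call, and with DESeq2, where 60 gained one. With this spread and 3 samples per group, 12% of simulated 1.5-fold changes were called, in genes above a minimum mean count. Other depths were not tried.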

Other observations

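The N-acetyltransferase genes of the Nat8 family, which encode enzymes that acetylate cysteine conjugates, had 4 of 8 tested members called higher and 0 lower. Nat8 rose by 2.89 ± 0.31 log2, Nat8f5 by 3.83 ± 0.55, Nat8f6 by 2.98 ± 0.32 and Nat8f2 by 1.80 ± 0.24 (edgeR adjusted p = 0.0136, 0.0345, 0.0145 and 0.0165). Nat8f6 is over 98% identical to Nat8f3 and Nat8f7 and shares exon bases with Nat8f5, so these members are not separate measurements. Carboxylesterases had 3 of 10 higher, Ces1f (3.46 ± 0.54), Ces1g (3.09 ± 0.46) and Ces2c (1.26 ± 0.23); Ces2c is 96.1% identical to Ces2d-ps over 85.5% of its transcript. Cytochrome P450 genes had 4 of 49 higher, and Slc16a1, a lactate transporter, was lower in DHT (-1.77 ± 0.21). The 10 families were picked after the largest changes had been seen, so no test of a family is given.

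Genes outside the fixed groups with the largest falls included Slc17a2, a phosphate transporter relative (14.4 ± 9.97 to 0.287 ± 0.219 CPM, pooled ratio 0.019 with a 95% exact interval of 0.0103 to 0.0321, control replicate 1 at 2.89 CPM), and Hdc, which makes histamine (11.3 ± 9.49 to 0.571 ± 0.395 CPM). Col7a1, anchoring fibril collagen, fell from 5.92 ± 1.94 to 1.09 ± 0.640 CPM and Loxl4, a collagen crosslinking enzyme relative, from 19.4 ± 13.6 to 1.17 ± 0.394 CPM (edgeR adjusted p = 0.0371 and 0.0457). With the length correction Hdc (log2 fold change -4.28 before and -4.20 after, adjusted p = 0.0527), Loxl4 (-4.04 and -4.02, 0.0556), Grin3b (-2.15 and -2.17, 0.0544) and Klf2 (1.01 and 0.88, 0.0588) passed the threshold no longer. Without DHT replicate 2 Slc17a2 (0.07), Hdc (0.0632) and Loxl4 (0.0887) did not pass, at log2 fold changes of -6.26, -4.72 and -4.36. Angptl7, Fmo5, Hrg and Nat8f5 were among the 12 largest rises. Grin3b shares 32.1% of its exonic bases with Tmem259 on the other strand. Several urothelium markers were high in control replicate 3 alone, with Krt15 at 7.27, Psca at 11.9 and Upk3a at 5.69 CPM against at most 0.519 CPM in the other libraries. Adrenal markers Cyp11a1 (6.33 CPM) and Hsd3b1 (6.48 CPM) were also highest there. Nr5a1 and Pnmt were found there only, at 0.0495 CPM each. Other members of that list did not follow. Cyp11b1, Cyp11b2, Cyp21a1 and Th had 0 CPM in all libraries. Star was at 2.47 CPM against 2.15 and 2.49 CPM in control replicates 1 and 2. Akr1b7 (2.08 CPM) and Fdx1 (39.4 CPM) were lowest in control replicate 3. Of 4 adrenal markers tested 1 was called, Akr1b7, an aldo-keto reductase, higher in DHT at 8.09 ± 2.59 against 2.74 ± 0.684 CPM (edgeR adjusted p = 0.0418). Akr1b7 did not pass with the length correction (log2 fold change 1.57 before and 1.37 after, adjusted p = 0.0698). Cyp11a1, Cyp11b1, Cyp11b2, Cyp21a1 and Hsd3b1 had 0 CPM in each DHT library, so the rise of Akr1b7 is not evidence of adrenal tissue there. Of 4 neutrophil and 2 skeletal muscle markers tested 0 were called, S100a9 standing at 1.99 ± 0.231 CPM in DHT and 0.607 ± 0.508 CPM in control (edgeR adjusted p = 0.174). Without DHT replicate 2 the adrenal list held 2 higher and 1 lower, without DHT replicate 1, DHT replicate 3, control replicate 2 or control replicate 3 it held 0, and without control replicate 1 the muscle list held 1 lower. Immediate early genes held 1 call of 21, Klf2, glucocorticoid genes 1 of 17, Tsc22d3, heat shock genes 0 of 10, interferon genes 0 of 29 and cell cycle genes 0 of 25. Without DHT replicate 2 the immediate early and glucocorticoid lists held 2 higher each, heat shock 4 higher, interferon 3 lower and cell cycle 1 higher. Without DHT replicate 1, DHT replicate 3 or control replicate 2 all 5 lists held 0. Without control replicate 1 the immediate early list held 0, the glucocorticoid list 2 higher and the interferon list 1 lower. Camera placed these lists higher, the interferon list lower (adjusted p = 0.000181, 0.0313, 0.028, 0.0297 and 0.000227), and 0 held with an estimated correlation (adjusted p = 0.669, 0.669, 0.868, 0.914 and 0.669). The interferon list did not part the groups, with library medians of -0.61, 0.03 and -0.44 in DHT replicates 1, 2 and 3 and -0.33, -0.12 and 0.47 in control replicates 1, 2 and 3, and 7 of 10 divisions of the libraries gave as small a p, the real one counted. DHT replicate 2 also overlapped controls in the heat shock list (0.04 against 0.06 in control replicate 3) and the glucocorticoid list (0.12 against 0.19 in control replicate 1). Cholesterol synthesis, fatty acid synthesis, gluconeogenesis, unfolded protein response, class II antigen presentation and mitochondrial respiratory chain lists held 0 calls and did not pass camera, with 3 fatty acid synthesis genes higher and 6 lower over the list alone. Without DHT replicate 2 fatty acid synthesis held 3 higher and 1 lower, cholesterol 2 higher and 1 lower, and gluconeogenesis and the unfolded protein response 1 higher each. Without control replicate 1 fatty acid synthesis held 4 lower and cholesterol 1 lower. Genes of the histocompatibility region in the class II and interferon lists were counted little, as near Tnf: H2-Ab1 averaged 12 counts per library, Psmb8 2 and Tap1 5, against 3161 for Cd74 elsewhere. H2-Aa averaged 44, with 216 in control replicate 3. The interferon list rests mainly on its other members. H2-Aa and H2-Ab1 were tested, however, and count among the 6 class II members. H2-Aa (log2 fold change -2.44) was the 1 below 0, and the list's mean was 0.146 against a median of 0.544. Among widely expressed genes Ppia averaged 70 and Gapdh 590 counts per library, against 9111 for Actb and 69806 for Eef1a1. COX1 averaged 898950 counts and COX2, COX3 and ATP6 1886, 928 and 677.

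The tests of the time of day, of the mixed sample, of the proximal tubule share and of an action on the clock were chosen only after their result had been seen, as were the length and GC corrections and the window around Tnf. The 437 gene calls compare with at most 0 in the other divisions, 1 of 10, the real one, reaching it, and the 15 list calls with at most 21, 7 of 10 reaching it, the real one counted. The 10 divisions of 6 libraries into 3 and 3 are too few for a share under 0.05. The other divisions also have unequal numbers of DHT libraries on their sides, so they are not free of the group difference.

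Clock genes moved apart between the groups. A length or GC trend between libraries is argued against: all 8 called clock genes stayed called in both corrected fits. Of 14 genes placed near or opposite Arntl in the daily cycle, 13 go with 1 shift, Cry1 (0.59 ± 0.32) being the exception. The count takes the sign alone. Among the 13, Clock, Nr1d1, Nr1d2, Dbp, Hlf and Bhlhe41 did not pass (edgeR adjusted p between 0.0559 and 0.12). Genes of 1 loop are also not independent observations. The shared shift fits collection at different times of day and an action of DHT on the kidney clock alike, so the pair cannot be told apart. No collection time is given in the labels. A difference in collection time could bear on calls outside the clock list too, and which of them it would touch was not tested.

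Short transcripts were higher and long transcripts lower in DHT. The trend was not confined to genes of the ribosome and respiratory chain, since rho was -0.218 over the 13966 genes left without them. Those genes are too few for leaving them out to move rho far, so the small change in rho is no further test. The fold change followed spliced length with genomic length held fixed (partial rho -0.165) and genomic length hardly (-0.009), which is consistent with a trend set in the library or by RNA quality. Another division of the libraries reached a rho of 0.240 in size, and after the length correction 249 genes were called. A DHT effect on short transcripts was not tested.

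DHT replicate 2 lay below the other DHT libraries in 18 of 20 androgen-raised genes, with a median of -1.80 log2 relative to them. Control RNA mixed in would leave the same share of the excess for each gene. Over the 7 members called, shares ran from 6.71% for Slco1a1 to 73.4% for Gusb. That is a ratio of 10.9 against 2.27 between DHT replicates 3 and 1. The calls used DHT replicate 2, so a member with a small rise passed more easily where that library kept its excess. The spread is thus partly built in and does not decide on mixing. Cyp2j13, Slc22a30, Cyp2e1 and Cyp4b1, with large rises, had 8.68%, 18.1%, 20.4% and 27.4%, and Timd2 51%. A share of the whole proximal tubule lower by as much as the androgen-raised genes is argued against. Proximal tubule markers had a median of -0.12, with quartiles of -0.43 and 0.22, and 11 of 25 lay below both other DHT libraries. Some of these markers differ with DHT themselves, 2 higher and 3 lower over the list alone, so a smaller loss is not excluded. The straight segment list stood at -0.43 in DHT replicate 2 against 0.39 and 0.96 in DHT replicates 1 and 3. Control replicate 1 was at -1.04 on that list. As the list holds Slc7a13, which rose with DHT, it does not part a lower share of that segment from a weaker response. In the same library 16 of 16 macrophage markers lay above both other DHT libraries, and a weaker exposure to DHT was not tested.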
